A study of Mus musculus with 6 samples.

How the data were processed

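Fibroblasts of both genotypes came from mid-gestation mouse embryos. Per the labels' protocols, RNA was taken at passage 0 after 2 days in culture, depleted of ribosomal RNA and read from both ends at 150 bp. The authors deposited a table of TPM, transcripts per 1000000, for Ensembl genes in 6 libraries, and each library's values sum to 1000000. Per the submitters' processing notes, the tools Trimmomatic, STAR, featureCounts, Subread and DESeq2 and the builds mm10 and GRCm38 were used, with no role, order or version given. The gene lengths behind the TPM values, the annotation release and the strand setting are not given in the sources used here. TPM is a share of each library, so a rise in abundant transcripts lowers all others, and total RNA without poly(A) selection also contains unspliced RNA. Antisense and overlapping genes cannot be told apart without the strand setting.

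Depth was estimated from the values. With exon-union lengths from GENCODE release M21 (GRCm38), TPM times length was a whole multiple of the value of 1 read, within 0.05, for 91.1% to 91.5% of the non-zero values under 100 reads. On this scale the libraries held 17500000 to 24600000 reads, and 1 read on a 100 nt gene was worth 1.48 to 2.12 TPM. Identifiers of 49056 genes matched the release, and 259 did not and held at most 0.021% of TPM. Among the genes listed, 174 had no symbol and 26 symbols had the form of a date, so list members with such symbols were not found. No pair of libraries was identical: at most 1 gene had the same non-zero value in any pair.

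Genes at TPM 1 or more in at least 3 libraries were tested, 14818 in all, on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend, no covariate, two-sided, and Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera from limma at a preset correlation of 0.01, adjusted over the 36 lists with at least 5 measured members, and again with an estimated correlation and with fry. Of 38 lists, those of sex-linked genes and erythroid genes, with 1 and 2 measured members, were not tested. The level of Acvr1 also had an exact permutation test. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for joining and plotting.

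The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 10 largest increases and the 10 largest decreases among genes past the threshold, with groups that did not overlap and a higher mean of at least 5 TPM, then Acvr1, then up to 4 members of each described list with the smallest unadjusted p. Unnamed gene models and pseudogenes were skipped, 1 among the increases and 2 among the decreases. Smad6, Tgif1 and Sox10 were named after their values were seen, to complete counts. So were Ibsp, Ifitm5, Alpl and Phospho1, to show downward members of the bone list, and Matn1, Cnmd and Comp, for the cartilage list. The genes called by voom in lists with no limma call were named after their values were seen too. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at TPM 5, median-of-ratios scaling, quantile normalization, TPM rescaled without the 50 highest and all mitochondrial genes, limma without the trend, with library weights or with the replicate number as a block, each library left out in turn, and other thresholds. Added after the data were seen were limma voom on reads rebuilt from TPM, leaving out replicate 2 of both genotypes, leaving out genes shorter than 300 nt, and camera without its mean-variance trend.

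The tests were checked on simulated reads for 14785 genes, for R206H against wild type, with 50 genes changed at each of 4 fold sizes. limma on log2(TPM + 1) recovered 10, 37, 49 and 50 of 50 at folds of 1.5, 2, 4 and 8, with 9 unchanged genes called, and voom recovered 26, 44, 50 and 50, with 7. camera called none of 100 lists of unchanged genes. With camera, a list of changed genes had an adjusted p of 1.88e-49 with the preset correlation and 0.0212 with an estimated one. The check did not cover lists whose genes move together, changed genes with few reads or a library that stands apart. Each simulated gene had the average spread of genes at its level and varied independently of the others. The recovered and false calls need not hold for the real genes outside these settings. In the real libraries the estimated correlation within lists ran from -0.043 for nuclear envelope genes to 0.691 for skeletal muscle markers. The check therefore cannot show how often the preset correlation gives false calls in correlated lists.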

Results

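RNA was sequenced from mouse embryonic fibroblasts, a mixed population of mesenchymal cells grown out of mid-gestation embryos. The series compared cells carrying 1 copy of the R206H allele of Acvr1 with wild-type cells. Acvr1 encodes a type I receptor for bone morphogenetic proteins (BMPs), and this amino acid change is the classical mutation of fibrodysplasia ossificans progressiva, a disease in which bone forms in soft tissue. Each genotype had 3 libraries, which the design text describes as biological replicates. The question stated in the design text was which transcripts differ with the mutation, and the series title places it in the context of BMP signalling, mechanical signalling, chromatin and bone formation. Values were TPM (transcripts per 1000000) for Ensembl genes. The estimated depth was 17500000, 24600000 and 22600000 assigned reads or read pairs in wild-type libraries 1, 2 and 3, and 21700000, 17800000 and 21200000 in R206H libraries 1, 2 and 3. Changes below are log2(TPM+1) in R206H minus wild type, which understates the change of weakly expressed genes, and ratios are of mean TPM. All SDs have n = 3.

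In R206H fibroblasts, 8 of 46 extracellular matrix genes, 5 of 29 BMP-responsive genes and 6 of 24 genes responsive to transforming growth factor beta (TGF-beta) were higher, and 2 of 18 epithelial markers were lower. As whole lists these 4 passed with camera at a preset correlation but had adjusted p = 0.489 with an estimated correlation and adjusted p = 0.0622 with fry. Of 14818 genes tested with limma, 303 passed a Benjamini-Hochberg adjusted p of 0.05, with 186 higher and 117 lower in R206H. The groups did not overlap in 32.9% of the genes tested, against 10% by chance for 3 against 3. The first principal component held 40.8% of the variance and separated the genotypes, with wild-type scores of -18, -20.3 and -29.1 and R206H scores of 7.2, 20.7 and 39.5. Wild-type library 1 stood apart from the other libraries on the second component, at 34.1 against a range of -16.3 to 4.8. The number of genes past the threshold changed when single libraries were left out. Without wild-type libraries 1, 2 and 3 in turn, limma gave 292 (226 higher, 66 lower), 4 and 1. Without R206H libraries 2, 3 and 1 in turn, it gave 0, 0 and 729. Genes at an unadjusted p under 0.05 numbered 3861 with all libraries and 3903, 2789, 2522, 3048, 2765 and 3996 in those fits. Many genes lay close to the threshold, as 303 passed at 0.05 and 1787 at an adjusted p under 0.10. Fits with a library left out also rest on fewer libraries. The groups did not overlap in any of the 303 genes, so leaving out a library could not reverse their direction, and none changed. The test on rebuilt read counts, limma voom, called 1290 of 14785 genes, 285 of them shared with limma. As a background for the lists below, 26.1% of all genes tested had an unadjusted limma p under 0.05.

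**Figure D1:**
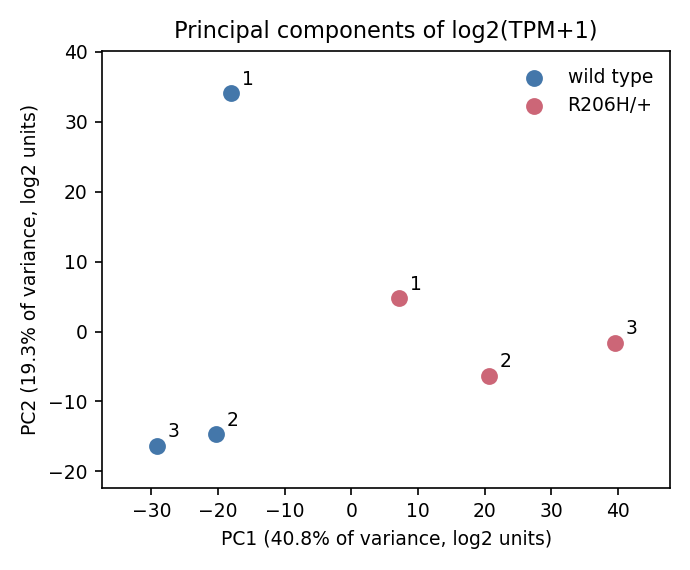
Scores of the 6 libraries on the first (x axis, 40.8% of the variance) and second (y axis, 19.3%) principal components of log2(TPM+1), in log2 units, with replicate numbers beside the points. The wild-type libraries lie between -29.1 and -18 on the first component and the R206H libraries between 7.2 and 39.5.

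Tnn, which encodes the matrix glycoprotein tenascin-N (ENSMUSG00000026725, chromosome 1, 160085029 to 160153580, GRCm38), was 12.8 times higher, at 37 ± 24.1 TPM against 2.88 ± 1.09 (SD, log2 change 3.13, SE 0.474, limma adjusted p = 0.0454). Without R206H library 3 the ratio was 8.3, and that of Apol6 was 7.7 instead of 12. The wild-type mean of Apol6 was 0.515 TPM, so the size of its ratio is uncertain. The small leucine-rich proteoglycans asporin (Aspn) and fibromodulin (Fmod) were 6.82 and 6.17 times higher, with log2 changes of 2.58 (SE 0.322, adjusted p = 0.0362) and 2.47 (SE 0.234, adjusted p = 0.0272). The chemokine gene Cxcl14 was 6.01 times higher and Prg4, which encodes the joint lubricant lubricin, 6.14 times. Tgfbi, a TGF-beta-induced matrix protein, reached 274.8 ± 105 TPM against 69.5 ± 6.29, and the growth factor gene Ptn 239.8 ± 74.2 against 66.3 ± 16.3. Apol6, Cacna1h, a T-type calcium channel subunit, and Lrrc17 completed the 10 largest increases, with log2 changes of 2.13, 1.67 and 1.66.

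Hsd3b6, a hydroxysteroid dehydrogenase, fell from 10.3 ± 7.97 to 0.527 ± 0.312 TPM (log2 change -2.67, SE 0.477, adjusted p = 0.0476). Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), fell from 7.45 ± 2.7 to 0.498 ± 0.538 TPM (log2 change -2.50, SE 0.34, adjusted p = 0.0417). Wild type was 19.5 times R206H for Hsd3b6, or 10.9 times without wild-type library 3. For Cyp1a1 it was 14.9 times, or 38.1 times without R206H library 1. R206H libraries 1, 2 and 3 had 0.5693, 0.8153 and 0.1952 TPM of Hsd3b6 and 1.104, 0.0753 and 0.3155 TPM of Cyp1a1. Such low values leave the size of both ratios uncertain. The tight junction gene Cldn3 had a log2 change of -1.82 (SE 0.182, adjusted p = 0.0272), the keratin gene Krt80 one of -1.47, and Msln, a mesothelial surface protein, fell from 104 ± 6.53 to 41.7 ± 16 TPM. Itgb7, Crct1 and Sdcbp2 had log2 changes of -1.79, -1.44 and -1.43. Prl2c3 and Prl2c2 had values of -1.79 and -1.65, but these proliferin genes have near-identical copies, so their separate levels are uncertain. All 20 of these genes were also called by limma voom. None of the 20 passed the threshold without wild-type library 3, R206H library 2 or R206H library 3, 1 did without wild-type library 2 and 10 did without wild-type library 1.

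**Figure D2:**
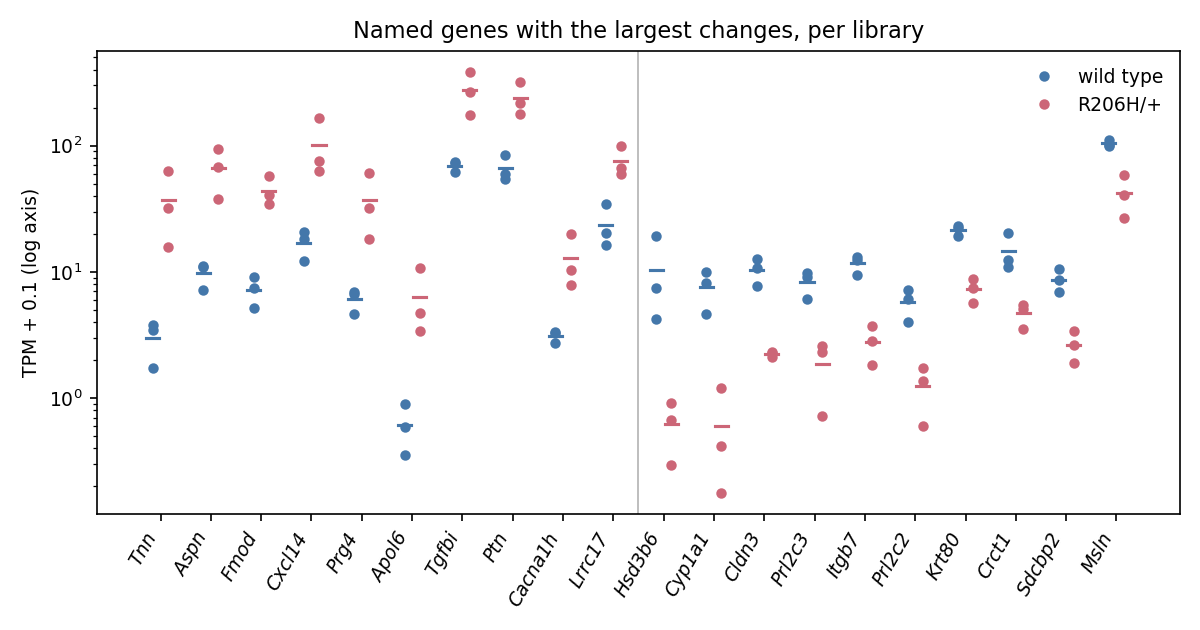
TPM plus 0.1 on a log axis for the 10 named genes with the largest increases (left of the line) and the 10 with the largest decreases (right), with a point per library and a bar at each group mean. The groups do not overlap for any of the 20 genes, and Tnn spans the widest change among the increases, with means of 2.88 and 37 TPM.

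Acvr1 itself (ENSMUSG00000026836, chromosome 2, 58388644 to 58567157) was measured at 44.4 ± 2.69 TPM in R206H and 34.7 ± 1.01 in wild type, a log2 change of 0.35 (SE 0.067) that did not pass the threshold (limma adjusted p = 0.0511). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. The adjusted p fell to 0.0312 with limma voom, 0.0403 without genes shorter than 300 nt and 0.0169 with library weights, over a range of 0.0169 to 0.365 across the alternatives computed for it. A single amino acid change need not alter the level, so this value does not check the genotype labels.

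Among BMP-responsive genes, 5 of 29 measured were higher, 1 was lower and 23 did not pass. Msx2, a homeobox gene induced by BMPs, rose from 15.3 ± 1.5 to 36 ± 5.24 TPM (log2 change 1.18, SE 0.121, adjusted p = 0.0272). Hand1 rose from 1.64 ± 0.099 to 6.32 ± 0.958 TPM, and Id3, an inhibitor of helix-loop-helix factors, from 322 ± 30.9 to 546.8 ± 57. Atoh8 was 2.06 times higher. The other called members were the inhibitory Smad gene Smad6, which was higher, and the corepressor gene Tgif1, which was lower. Adjusted over the list alone, 12 were higher and 2 lower. The list as a whole had a median log2 change of 0.40 (camera adjusted p = 3.31e-05, and adjusted p = 0.489 with an estimated correlation). Of 34 BMP and activin ligands, receptors, SMADs and associated regulators, 2 were higher: the ligand gene Bmp4, at 233.6 ± 40.4 against 109.8 ± 17.9 TPM, and Fstl1, at 1174 ± 118 against 738.5 ± 92.2. The co-receptor gene Rgmb had a log2 value of -0.37 that did not pass (adjusted p = 0.0671). That list did not differ from other genes (camera adjusted p = 0.466), with 6 higher and 3 lower adjusted over the list alone. Of 24 TGF-beta-responsive genes, 6 were higher and 1 lower, or 11 and 1 adjusted over the list alone. The lower one was Tgif1, the same gene as in the BMP list. The higher genes included Tgfbi, Tgfb3, a ligand of the pathway, at 1.68 times, and the transcription factor gene Snai1 at 1.92 times. The collagen-binding integrin gene Itga11 was 2.21 times higher. This list had a median of 0.25 (camera adjusted p = 4.27e-04, and adjusted p = 0.489 with an estimated correlation). Alongside these lists, epithelial markers had a median of -1.10. The share of TPM from mitochondrially encoded genes was 3.43% to 3.85% in R206H against 4.16% to 4.57% in wild type. Here and below, this share covers all mitochondrially encoded genes, including transfer RNA genes, and not only those coding for protein.

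The matrix list had 8 of 46 measured genes higher and 1 lower, or 30 and 2 adjusted over the list alone, and a median log2 change of 0.51 (camera adjusted p = 2.06e-11, and adjusted p = 0.489 with an estimated correlation). Fbln5, an elastic fibre protein, had a log2 change of 0.75 (SE 0.084, adjusted p = 0.0315). Aspn is given above. The proteoglycan gene Bgn rose from 770.8 ± 36.2 to 1099 ± 77.4 TPM and the fibrillar collagen gene Col5a2 from 328.7 ± 24.2 to 502.9 ± 50.8. Of 12 tendon genes, 2 were higher, Fmod and the tendon surface protein gene Tnmd, the latter at 48.4 ± 5.03 against 18.9 ± 3.08 TPM. Abi3bp and Mkx had log2 values of 1.66 and 0.64 that did not pass (adjusted p = 0.0727 and 0.141). The tendon list had a median of 0.34, with 3 higher adjusted over the list alone (camera adjusted p = 0.00115, and adjusted p = 0.489 with an estimated correlation). In the same libraries the epithelial marker list had a median of -1.10, and mitochondrially encoded genes took 3.43% to 3.85% of TPM in R206H against 4.16% to 4.57% in wild type.

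Bone and cartilage genes had values in both directions. Of 29 bone genes, 1 was higher, Ogn, which encodes the proteoglycan osteoglycin, at 126.3 ± 34.5 against 43.8 ± 7.78 TPM (log2 change 1.48, SE 0.225, adjusted p = 0.0454). The matrix genes Postn, Col1a2 and Col1a1 had log2 values of 0.86, 1.08 and 1.20 that did not pass (adjusted p = 0.0501, 0.0617 and 0.0655). The largest value in the list was downward: Ibsp, which encodes bone sialoprotein, had 5.6 ± 7.36 against 50.1 ± 25.4 TPM (log2 -3.48, adjusted p = 0.0735). Its R206H libraries 1, 2 and 3 had 0.331, 14 and 2.47 TPM. Wild type was 8.95 times R206H for Ibsp, or 6.09 times without R206H library 1 and 35.9 times without R206H library 2. The mineralization genes Ifitm5, Alpl and Phospho1 had log2 values of -1.29, -1.18 and -0.79 that did not pass either (adjusted p = 0.11, 0.117 and 0.0801). Wild type was 5.38 times R206H for Ifitm5, or 3.59 times without R206H library 2 and 8.51 times without R206H library 3. R206H libraries 1, 2 and 3 had only 0.67, 0 and 0.92 TPM of Ifitm5, so its ratio is uncertain. For Alpl, wild type was 2.89 times R206H, or 2.24 times without wild-type library 2 and 4.44 times without R206H library 2. Adjusted over the list alone, 12 were higher and 6 lower. The bone list had a median of 0.41 and a mean of 0.15 (camera adjusted p = 0.0168, and adjusted p = 0.588 with an estimated correlation), and did not pass without R206H library 2 (median 0.41, adjusted p = 0.0613). The epithelial median beside it was -1.10. Of 27 cartilage genes, 3 were higher, Fmod, Prg4 and Col11a1, also adjusted over the list alone, and the list had a median of -0.23 (camera adjusted p = 0.571, and 0.0307 without wild-type library 1). Of the 27 values, 11 were positive and 16 negative. Among the negative ones, the fibrillar collagen gene Col11a2 had a log2 value of -1.54 that did not pass (adjusted p = 0.0939). Matn1, Cnmd and Comp had -2.27, -1.81 and -1.45 and did not pass either (adjusted p = 0.159, 0.158 and 0.236). The cartilage list's library medians overlapped between the genotypes. They were -0.43, 0.11 and 0.38 in wild-type libraries 1, 2 and 3 and -0.33, 0.12 and -0.14 in R206H libraries 1, 2 and 3.

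**Figure D3:**
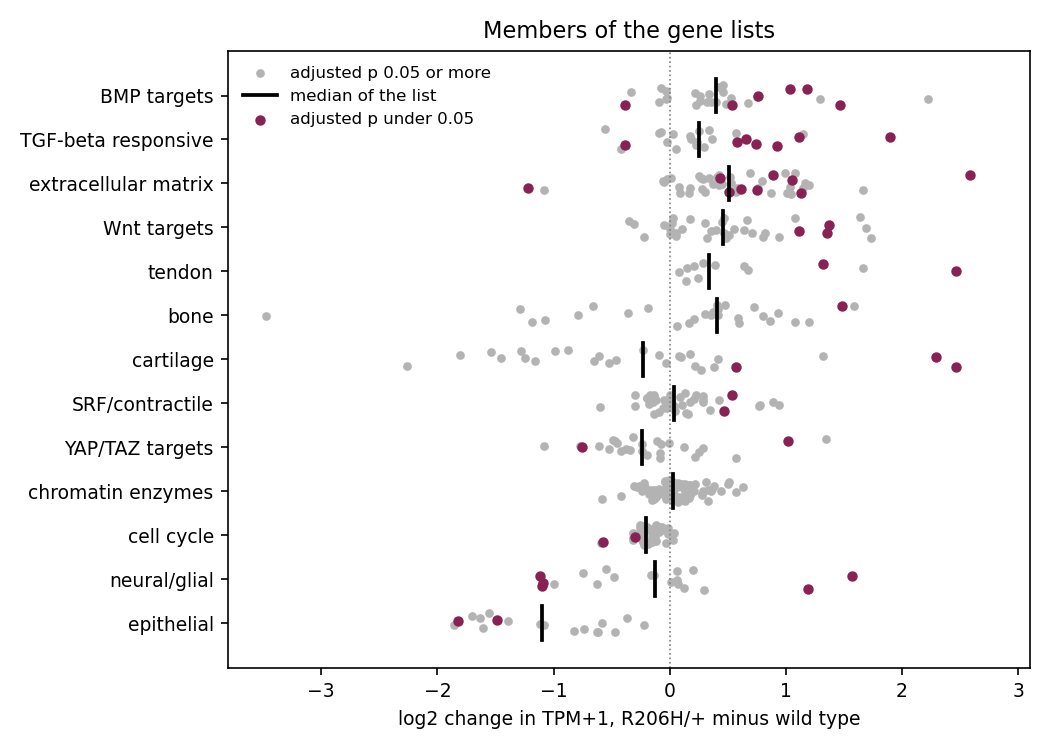
Log2 changes in TPM+1 (x axis, R206H minus wild type) of the measured members of 13 gene lists, with a point per gene, dark points for genes past the adjusted p of 0.05 and a vertical bar at each list's median. The medians range from -1.10 for epithelial markers to 0.51 for extracellular matrix genes, and the chromatin enzymes centre on 0.03.

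Of 35 Wnt pathway targets and regulators, 3 were higher. These were the Wnt antagonist genes Sfrp1, at 75.7 ± 9.97 against 34.7 ± 5.96 TPM, and Notum, at 10.2 ± 3.04 against 3.26 ± 0.456, and the Wnt potentiator gene Rspo2, at 14.1 ± 3.32 against 4.95 ± 1.77. The ligand gene Wnt5a had a log2 value of 0.33 that did not pass (adjusted p = 0.0638). The list had a median of 0.46, with 16 higher adjusted over the list alone (camera adjusted p = 3.1e-05, and adjusted p = 0.489 with an estimated correlation). Its library medians, taken over each gene's difference from its mean across libraries, were -0.14, -0.20 and -0.39 in wild-type libraries 1, 2 and 3 and 0.08, 0.14 and 0.40 in R206H libraries 1, 2 and 3, against 0.98, 0.19 and 0.50 and then -0.10, -0.50 and -0.73 for epithelial markers, and mitochondrially encoded genes took 3.43% to 3.85% of TPM in R206H against 4.16% to 4.57% in wild type. None of 15 hedgehog genes passed with limma, with 6 at an unadjusted p under 0.05 and 4 called by voom, Boc, Cdon and Gli3 higher and Hhip lower, and the list had a median of 0.20 (camera adjusted p = 0.0168, and adjusted p = 0.492 with an estimated correlation). The co-receptor gene Boc had a log2 value of 0.86 (adjusted p = 0.0509), and 4 genes were higher and 1 lower adjusted over the list alone. None of 12 Notch genes passed with limma, with 4 at an unadjusted p under 0.05 and 4 called by voom, Hes1, Notch1 and Notch3 higher and Rbpj lower (camera adjusted p = 0.167, and 0.0176 without wild-type library 1). Hes1 had a log2 value of 0.36 (adjusted p = 0.0511), and 2 were higher and 1 lower adjusted over the list alone.

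For mechanical signalling, the 27 targets of YAP and TAZ, the coactivators held back by the Hippo pathway, had 1 gene higher and 1 lower. Ccdc80 rose from 144.8 ± 7.87 to 299.4 ± 66.5 TPM and Nt5e fell from 7.56 ± 0.613 to 4.09 ± 0.571. Wwc1 and Birc5 had log2 values of -0.61 and -0.31 that did not pass. The list had a median of -0.24, with 4 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.489 with an estimated correlation), beside -1.10 for epithelial markers. Of 23 Hippo pathway components, 1 was lower, the transcription factor gene Tead4, at 14.2 ± 1.96 against 24.1 ± 2.23 TPM. The kinase gene Lats2 had a log2 value of -0.47 (adjusted p = 0.0635), and 5 were higher and 5 lower adjusted over the list alone (camera adjusted p = 0.447). Of 41 genes of the contractile apparatus and serum response factor, 2 were higher, Csrp2 at 1.45 times and the non-muscle myosin gene Myh10 at 1.38 times, or 6 adjusted over the list alone (camera adjusted p = 0.318, and 3.83e-04 upward without R206H library 3). Of 41 focal adhesion genes, Itga11 was higher and the laminin-binding integrin gene Itga3 was lower, at 75.9 ± 17.9 against 144.9 ± 15.9 TPM, and 6 were higher and 7 lower adjusted over the list alone (camera adjusted p = 0.216).

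Chromatin enzymes showed no gene past the threshold with limma among 83 measured, either over all genes or adjusted over the list alone (camera adjusted p = 0.498, median 0.03). At an unadjusted p under 0.05 there were 22, and voom called 3 higher and 4 lower. Both counts are close to the shares over all genes, 26.1% at that p and 1290 of 14785 called by voom. The remodeller genes Chd3 and Smarca1 had log2 values of 0.57 (adjusted p = 0.0501) and 0.63 (adjusted p = 0.0655). Dot1l and Suz12, genes of histone methyltransferase complexes, had values of -0.26 and -0.28 (adjusted p = 0.0671 and 0.077). None of 19 nuclear envelope genes passed with limma, with 4 at an unadjusted p under 0.05 and 3 called by voom, Banf1, Syne3 and Tmpo (camera adjusted p = 0.485), with 1 higher and 2 lower adjusted over the list alone. Tmpo had a log2 value of -0.37 (adjusted p = 0.0543). Of 32 replication-dependent and related histone genes, Hist1h4k and Hist1h1c were higher and Hist1h2ac was lower, also adjusted over the list alone (camera adjusted p = 0.363). Histone genes have near-identical copies, so these 3 levels are uncertain.

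Of 45 cell cycle genes, 2 were lower in R206H, E2f8, at 17.6 ± 2.22 against 26.6 ± 0.63 TPM, and the mitotic regulator gene Foxm1, at 51.2 ± 1.95 against 63.1 ± 0.899, or 13 adjusted over the list alone. Pcna had a log2 value of -0.26 that did not pass (adjusted p = 0.0501). The list had a median of -0.20 (camera adjusted p = 2.06e-11, and adjusted p = 0.489 with an estimated correlation). Of 22 p53 and senescence genes, 1 was higher, the cell cycle inhibitor gene Cdkn2b, at 156.6 ± 19.4 against 98.6 ± 9.07 TPM, or 9 higher and 2 lower adjusted over the list alone. Cdkn2b is also among the called TGF-beta-responsive genes. That list had a median of 0.18 (camera adjusted p = 0.0345, and adjusted p = 0.5 with an estimated correlation), and did not pass without wild-type library 2, wild-type library 3, R206H library 1 or R206H library 2 (medians 0.17, 0.16, 0.21 and 0.20, adjusted p = 0.0564, 0.0599, 0.0509 and 0.0869). Beside both lists, the epithelial median was -1.10 and mitochondrially encoded genes took 3.43% to 3.85% of TPM in R206H against 4.16% to 4.57% in wild type. Of 31 immediate early genes, Socs3 was 2.28 times higher and Myc was lower, at 74.3 ± 10.3 against 115.2 ± 1.32 TPM, or 7 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.498). None of 27 hypoxia and glycolysis genes passed with limma, also adjusted over the list alone, with 11 at an unadjusted p under 0.05 and 3 called by voom, P4ha1, P4ha2 and Ndrg1 (camera adjusted p = 0.485).

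None of the 13 mitochondrially encoded genes passed with limma, with 7 at an unadjusted p under 0.05 and 4 called lower by voom, mt-Nd1, mt-Nd2, mt-Nd5 and mt-Nd6, and all 13 were lower in value, with a median of -0.37 (camera adjusted p = 3.44e-05, and adjusted p = 0.489 with an estimated correlation). Adjusted over the list alone, 5 were lower. Of the 13, 6 averaged 8.19 to 55.1 TPM over the libraries, with a median of -0.41, and the other 7 averaged 1130 to 13300, with a median of -0.29, a division made after the values were seen. The 6 held 0.338% of the list's TPM, and their levels and changes are uncertain, for a reason that was not tested. The complex I gene mt-Nd1 had 5475 ± 477 against 7053 ± 321 TPM. These 13 genes code for protein, whereas the mitochondrial shares of TPM in other paragraphs also include transfer RNA genes. None of 86 ribosomal protein genes, 36 proteasome genes or 80 nuclear-encoded respiratory chain genes passed with limma, also adjusted over the list alone, with medians of -0.05, -0.04 and -0.04. At an unadjusted p under 0.05 there were 3, 6 and 10, and voom called 0, 0 and 2, the respiratory chain genes Cox6b2, higher, and Ndufa12, lower. Their camera adjusted p was 0.00201, 0.0117 and 0.0315, and with an estimated correlation adjusted p = 0.769, 0.586 and 0.691. These calls changed when single libraries were left out. Ribosomal protein genes did not pass without wild-type library 2, wild-type library 3 or R206H library 2 (medians -0.04, -0.03 and -0.03, adjusted p = 0.101, 0.0599 and 0.0613) and had -0.10 without wild-type library 1. Proteasome genes did not pass without wild-type library 2 (-0.04, adjusted p = 0.101) and had -0.07 without wild-type library 1, and respiratory chain genes did not pass without wild-type library 3 or R206H library 2 (-0.01 in each, adjusted p = 0.149 and 0.465). The library medians of ribosomal protein and respiratory chain genes overlapped between the genotypes. The epithelial markers had a median of -1.10 in the same comparison.

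Of 18 epithelial markers, 2 were lower, Cldn3 and the adhesion molecule gene Epcam, at 0.904 ± 0.0582 against 4.52 ± 1.87 TPM, or 13 adjusted over the list alone. The median was -1.10 (camera adjusted p = 2.03e-09, and adjusted p = 0.489 with an estimated correlation). Of 33 fibroblast and mesenchyme genes, 1 was higher, the craniofacial homeobox gene Alx1, or 16 higher and 1 lower adjusted over the list alone. That list had a median of 0.50, or 0.30 without wild-type library 1 (camera adjusted p = 2.3e-04, and adjusted p = 0.489 with an estimated correlation). In the same libraries mitochondrially encoded genes took 3.43% to 3.85% of TPM in R206H and 4.16% to 4.57% in wild type. Of 12 pericyte and smooth muscle markers, 1 was higher, the pericyte gene Rgs5, at 23.1 ± 1.68 against 9.77 ± 2.33 TPM, or 6 adjusted over the list alone. That list had a median of 0.72 (camera adjusted p = 6.24e-04, and adjusted p = 0.489 with an estimated correlation). Of 19 neural and glial markers, the neuronal genes Prph and Tubb3 were higher and Foxd3, Ngfr and Sox10, genes of neural crest and glia, were lower (median -0.13, camera adjusted p = 0.0726, and 0.0289 without R206H library 1 and 0.0448 without R206H library 3). Prph rose from 1 ± 0.045 to 4.95 ± 0.612 TPM and Ngfr fell from 39.8 ± 2.61 to 18.3 ± 5.51, and 2 were higher and 6 lower adjusted over the list alone.

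No gene passed with limma among 16 macrophage, 9 endothelial and 26 skeletal muscle markers, including adjusted over the list alone, with 2, 2 and 0 at an unadjusted p under 0.05, none called by voom, medians of 0.09, -0.18 and -0.21 and camera adjusted p = 0.362, 0.307 and 0.0545. The macrophage median was 0.32 without R206H library 3 (camera adjusted p = 3.83e-04) and -0.09 without R206H library 1. The skeletal muscle median was -0.43 without R206H library 1 (camera adjusted p = 9.89e-07) and -0.29 without wild-type library 2 (0.044). Of 19 adipocyte genes, the desaturase gene Scd1 was higher and the lipid droplet gene Plin2 lower, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.75). None of 21 interferon-responsive genes passed with limma, with 9 at an unadjusted p under 0.05, 5 higher and 1 lower by voom, a median of 0.37 and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00665, and adjusted p = 0.651 with an estimated correlation). Its library medians overlapped between the genotypes, at 0.12 in wild-type library 1, -0.35 and -0.42 in wild-type libraries 2 and 3, and 0.09, 0.25 and 0.33 in R206H libraries 1, 2 and 3, and without wild-type library 1 the list's median was 0.71. Of 25 inflammatory genes, the chemokine gene Cxcl12 was higher, or 1 higher and 3 lower adjusted over the list alone. The inflammatory list's median was 0.04 while its mean of -0.05 and the direction of its test were downward (camera adjusted p = 0.447). Of 36 Hox genes, 1 was higher, Hoxd10, also adjusted over the list alone, at 21.9 ± 2.83 against 13.8 ± 0.611 TPM (camera adjusted p = 0.106, and 0.00384 without R206H library 3).

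Across the 36 lists, 18 passed with the preset correlation, 11 upward and 7 downward, and the library medians overlapped between the genotypes in 3 of the 18, those of interferon-responsive, ribosomal protein and nuclear-encoded respiratory chain genes. With an estimated correlation none passed, the lowest adjusted p being 0.489 and the lowest unadjusted p 0.0657. None passed with fry, which asks whether a list's genes move one way on balance, at a lowest adjusted p of 0.0622.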

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

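The direction of the 303 genes held in every alternative in which they were tested. Their groups did not overlap, so leaving out libraries or changing the pseudocount, filter or library weights could not reverse it. The number of genes did not hold, and the cause was not tested except where stated. Against 303, the count was 129 (92 higher, 37 lower) with a pseudocount of 0.1, 2 with no filter on low values, where 27190 genes were tested, 587 with a filter at TPM 5, 200 with quantile normalization, 27 with limma without the trend, 1906 with library weights, 1787 at an adjusted p under 0.10 and 113 when a change of at least 1 was also required. Leaving out single libraries gave 0 to 729. Of the alternatives chosen after the data were seen, voom on rebuilt reads gave 1290, leaving out replicate 2 of both genotypes gave 0 by limma (1848 at an unadjusted p under 0.05, with fewer libraries), leaving out genes shorter than 300 nt gave 649, and camera without its trend gave 17 lists. Other scalings moved the share of higher calls, 61.4%, by less than 10 points, but it was 71.3% with a pseudocount of 0.1 and 77.4% (226 higher, 66 lower) without wild-type replicate 1.

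Deviations of same-numbered libraries correlated at 0.018, 0.06 and -0.028, against -0.052 to 0.03 for differently numbered ones, and not every library correlated best with its own number. The highest value, 0.06, was that of the libraries numbered 2, which alone had no Xist and expressed the Y-linked gene Ddx3y. Number 2 therefore tied libraries alike in sex-linked genes, and correlations this low cannot exclude a pairing. With the replicate block, limma called 0 genes (3301 at an unadjusted p under 0.05), 0 list members and 0 of the 20 largest changes.

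The number of list members past the threshold, 57, became 32 with a pseudocount of 0.1, 0 with no filter, 101 with a filter at TPM 5, 5 without the trend, 243 with library weights, 189 with voom, 0 without replicate 2 of both genotypes, 110 without genes shorter than 300 nt and 0 to 127 without single libraries. Of the 20 largest changes, 10 passed with a pseudocount of 0.1, 0 with no filter, 2 without the trend, 0 without replicate 2 of both genotypes and 0 to 18 without single libraries. The 18 lists past the threshold became 0 with an estimated correlation and 0 with fry, 12 without replicate 2 of both genotypes, and 14 to 22 without single libraries. Acvr1 passed with library weights (log2 0.40), with voom (0.33) and without short genes (0.35), and ranged from 0.30 to 0.39 without single libraries. The first principal component, 40.8% of the variance, took 31.9% with a pseudocount of 0.1, 50.8% with 5, 32.5% with no filter, 53.7% with a filter at TPM 5, 55.5% without replicate 2 of both genotypes, 49.9% without short genes and 38.9% to 50% without single libraries.

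Reversals were limited to 6 lists that passed in no such fit. The test of cartilage genes turned upward with a filter at TPM 5 (median 0.16), without wild-type replicate 2 (-0.07), without wild-type replicate 3 (-0.09), without R206H replicate 1 (-0.19) and with fry (-0.23). Contractile genes turned downward without R206H replicate 1 (-0.02), as did macrophage markers (-0.09). Chromatin enzymes turned downward without wild-type replicate 2 and without replicate 2 of both genotypes (-0.01 in each). Inflammatory genes turned upward with library weights (0.26) and without wild-type replicate 1 (0.28). Adipocyte genes turned upward with a filter at TPM 5 (0.10), with library weights (0.15), without wild-type replicate 1 (0.18) and without R206H replicate 3 (0.05). Without single libraries the medians ran from -0.26 to -0.07 for cartilage, -0.02 to 0.12 for contractile, -0.09 to 0.32 for macrophage, -0.01 to 0.07 for chromatin, -0.15 to 0.28 for inflammatory and -0.23 to 0.18 for adipocyte genes. Depth limits the short and weakly expressed genes, where 1 read on 100 nt is worth up to 2.12 TPM.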

Other observations

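In this part, the lists of ribosome biogenesis, sterol synthesis and collagen processing genes, the limit put on the share near Acvr1, and the tests of macrophage markers, of epithelial repressors, of short genes and of the region around Acvr1 were chosen after the results were seen. Genes named here were also chosen after their values were seen.

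All 50 measured ribosome biogenesis genes had lower values in R206H, with a median log2 change of -0.33 and 5 past the threshold (Nop16, Gnl3, Wdr12, Lyar and Eif6). Over 19 alternatives the median stayed between -0.37 and -0.28. The nucleolar protein genes Ncl and Npm1 had 313.9 ± 46.2 against 445.1 ± 30.5 TPM and 1250 ± 147 against 1647 ± 123 (SD, n = 3), neither past the limma threshold (adjusted p = 0.0635 and 0.0761). All 24 sterol synthesis genes had higher values, with a median of 0.61 (0.49 to 0.73 over the alternatives) and 3 past the threshold, Pmvk, Fdps and Nsdhl.

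Genes for collagen folding, modification and export had higher values in 32 of 36 cases, with a median of 0.42 (0.37 to 0.47 over the alternatives) and 8 past the threshold. They included the prolyl hydroxylase gene P4ha3 (log2 change 1.01, limma adjusted p = 0.006), Plod3, which hydroxylates collagen lysines, and the endoplasmic reticulum prolyl isomerase gene Fkbp10. These 3 lists were drawn up after the calls were seen, so a test of the whole lists would restate the calls, and a test of the rest is not independent of them. Without the called members, the medians of ribosome biogenesis, sterol synthesis and collagen genes were -0.32, 0.57 and 0.38. With camera adjusted over these 3 reduced lists, adjusted p = 2.88e-22, 1e-11 and 2.14e-07, and with an estimated correlation adjusted p = 0.151 for each. In the same libraries epithelial markers had a median of -1.10, and mitochondrially encoded genes took 3.43% to 3.85% of TPM in R206H against 4.16% to 4.57% in wild type.

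Among the 303 genes past the threshold, 16 had an exon length under 300 nt, and in 13 of these the higher group averaged fewer than 10 rebuilt reads per library. The gene with the smallest adjusted p of all, Gm22770 (67 nt, limma adjusted p = 0.00289), had 4, 3 and 3 reads in R206H and 0 in each wild-type library, and Mir1258 (60 nt) had 1 read in each R206H library and 0 in the others. Small read numbers on short genes, whose TPM moves in large steps, may account for some of those 13 calls, but 3 of them also passed with voom, which weights by read number: Gm22770 (voom adjusted p = 0.0335), Gm27651 (0.0488) and Gm11474 (0.0496). Of all 16, 4 passed with voom, and no biological explanation was tested. The count of all genes was 649 without genes shorter than 300 nt, with 14190 genes tested, and why it rose was not tested.

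Of 18 epithelial markers, 2 passed, both lower, and the list's median was -1.10 (camera adjusted p = 2.03e-09, and adjusted p = 0.489 with an estimated correlation and 0.0622 with fry). A lower share of every cell type other than fibroblasts stays open. Macrophage markers had a median of 0.09 (16 genes against 18, two-sided permutation p over genes = 1.9e-04), which met the bound written against this explanation. By limits added after that result was seen, it decides nothing: 14 of the 16 averaged under 10 TPM and their library medians overlapped, from -0.20 to 0 in wild type and -0.37 to 0.39 in R206H. Endothelial, skeletal muscle and neural or glial markers had medians of -0.18, -0.21 and -0.13, and pericyte and smooth muscle markers, several of which fibroblasts also express, 0.72. Fewer epithelial cells may account for part of this: 23 other epithelial genes had a median of -0.43, and 18 of them were lower in value (rank-sum permutation p over genes = 1e-05, the smallest the permutations can give). This median, however, lies between the bounds of -0.5 and -0.25 set before it was computed, and Cdh3 was higher. Both permutation tests treat genes as independent, whereas the estimated correlation was 0.464 among the 18 epithelial markers and 0.668 among macrophage markers. Lower epithelial expression within the same cells also stays open: 2 of 6 transcription factors that repress epithelial genes, Snai1 and Snai2, were higher in R206H, but both were already called in the TGF-beta list when that count was chosen, so it tests nothing. Bulk values leave these 3 explanations unseparated, and Klf5 and Jup, at 57.3 and 52.6 TPM in wild type, are also expressed at 43.7 and 55.2 TPM in R206H.

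Acvr1 was 1.28 times higher, short of the threshold. DNA of a donor strain around the targeted allele may alter expression nearby, which would raise the share of changed genes there. Of 145 genes within 20 Mb of Acvr1, 24.8% had an unadjusted p under 0.05, against 26.1% of 14672 genes elsewhere (Fisher's exact test, two-sided p = 0.776), and 3 were past the threshold. The share lay below that elsewhere, which met the bound written against this explanation, but its exact 95% interval of 18% to 32.7% includes the share elsewhere, so an excess too small for 145 genes stays open. An effect of the mutation on its own gene was not tested.

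The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The genotypes gave 303 genes, and the highest of the other splits gave 1; 1 split, the real one, gave as many.

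Xist, the transcript of the inactive X chromosome, was at 96.9 and 90.7 TPM in wild-type libraries 1 and 3 and 89.5 and 110.4 in R206H libraries 1 and 3, and at 0 in library 2 of each genotype. The Y-linked gene Ddx3y was at 48.2 and 52.2 TPM in those libraries 2 and at 0 in the other 4.

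The mitochondrial genes mt-Atp6, mt-Co2, mt-Atp8, mt-Nd4l, mt-Co3 and mt-Nd3 averaged 8.19, 9.85, 12.1, 17.3, 17.4 and 55.1 TPM over the 6 libraries, against 13300 for mt-Co1 and 7690 for mt-Cytb. Why these 6 genes were so much lower was not tested, so their levels and changes are uncertain.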
